A study of Oryza sativa with 6 samples.

How the data were processed

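Total RNA from roots of 30-day plants was labelled, per the labels, by the array maker's standard protocol from 6 ug of RNA, and hybridised to 1 Affymetrix rice array per sample. Samples were grouped by genotype from their titles, HH1 with 3 replicates and MH63 with 3, which the labels call biological replicates. The values are the deposited probe set intensity on a linear scale, 1 signal per probe set and array. The submitters' processing notes name MAS5, with no version. The values do not settle the method. Of 57943 signals above 300, 9.03% had a fractional part within 0.0002 of a common step of 1/12, where 0.48% is expected by chance, and means trimmed by 2% at each end ran from 161 to 170 between arrays. Such features are more usual for summaries fitted across arrays than for MAS5, so how the arrays were scaled and summarised is uncertain, and a summary fitted across arrays would lower the spread of dim signals. The table gives no detection calls.

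Signals were used as log2 values without an offset or further normalization. The 187 control probe sets (123 AFFX and 64 RPTR) were set aside, and of the other 57194 the brighter 50% by mean log2 signal over all 6 arrays, 28597 probe sets, were tested. The genotypes were compared in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with a trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The test, the filter, the rule for named genes and most processing alternatives were fixed before the data were examined. As a background level, the 95th percentile of the 64 reporter probe sets on each array was used, from 37.1 to 42.3. Where a group was at or below it on all 3 arrays, the fold is given as a bound, the bright group's mean log2 signal against the dim group's mean of the higher of its own signal and that level. This level was chosen after the data were seen.

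Probe sets were named through the platform annotation and Entrez gene numbers, with symbols and gene order from the RefSeq annotation of assembly ASM3414082v1. The genome build behind the array's probe sets is not given in the sources used here, so that annotation served only for names and gene order, and no coordinates are printed. Of probe sets in the annotation, 22436 had 1 gene and 95 had several, and 34663 non-control probe sets were not listed and are unnamed here. All 17905 genes matched by number, and 2458 of them had a name or synonym beyond a locus number. Gene lists had been planned by searching gene descriptions, but the annotation holds none, so those 30 lists could not be formed. They were replaced by 35 lists formed from gene names and synonyms, written after the files were opened and before any comparison between genotypes was computed. These lists cover 1022 of the 14815 genes tested. Each gene was represented by its brightest probe set, and lists of at least 5 measured genes were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the 35 lists, with an estimated correlation and fry beside it.

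Named genes followed a rule. They are the 12 largest increases and the 12 largest decreases past the test with groups that do not overlap and exactly 1 gene (planned as 1 gene with a description), or all where fewer passed, filled to 8 by smallest p; up to 4 members with the smallest p of each list past its test; the 4 brightest reference genes; and up to 2 increases and 2 decreases among probe sets without a gene, whose IDs are not printed. Probe sets whose ID ends in _s_at or _x_at can bind several related transcripts, and their genes are uncertain. Among the list genes and reference genes named, OsABCG37, OsABCG44, CYP76M8, OsPDIL2-3, OsPDIL2-1, EF-1-alpha and GAPC were read from such probe sets.

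The fit was tested on simulated arrays with the real means and spreads of the 28597 probe sets and 200 changed ones. For this comparison it recovered 35.8% of changes of 1 on the log2 scale, 77.6% of changes of 2 and 92.4% of changes of 3, with 9 false calls, and made 0 calls where nothing was changed. The spread was drawn independently for each probe set, so variation that many probe sets share on an array was not simulated. These counts therefore do not show how many false calls the real arrays give. With 1 list of 29 independent members shifted by 0.5, over 14815 genes, camera with the preset correlation and fry called that list and camera with an estimated correlation did not. This was 1 simulated case, and power over lists was not measured.

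Alternatives covered quantile normalization, median centring, no brightness filter, the brightest 25%, an offset of 13.2 (the 25th percentile of all signals), eBayes without a trend, array weights, a replicate block, leaving out each array in turn, and all 10 splits of the 6 arrays. For lists they also covered the mean of a gene's probe sets, but not median centring, the brightest 25%, eBayes without a trend or array weights. Figures were drawn with matplotlib 3.10.9.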

Results

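Root transcripts of the transgenic rice line Huahui 1 (HH1) and of its non-transgenic parent Minghui 63 (MH63) were measured on Affymetrix rice arrays at a plant age of 30 days. Each genotype had 3 biological replicates with 1 array each, 6 arrays in all, and the labels put seedlings of both genotypes in nutrient solution in a climate chamber. The value table held 57194 probe sets per array besides 187 controls. Median signals were nearly equal, from 33.1 in MH63 replicate 1 to 33.9 in MH63 replicate 2, and the 95th percentile ran from 1080 in MH63 replicate 3 to 1155 in HH1 replicate 2. The number of arrays limits the precision of every value below. The stated purpose of the series was to look for differentially expressed genes and changed pathways in HH1 roots as a lead to unintended effects of the transformation. The transgene's own transcript was not analysed here.

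Between genotypes, 32 of the 28597 probe sets tested differed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), of which 24 were higher and 8 lower in HH1. They stood for 20 genes, 14 higher and 6 lower, and 9 of the probe sets had no gene in the annotation used. OsSTLP5, a sialyltransferase-like protein, was the only called gene with a name. It rose from a signal of 75.1 ± 7.97 (SD, n = 3) in MH63 to 291 ± 23.0 (SD, n = 3) in HH1, a log2 change of 1.96 with a standard error of 0.14 and an adjusted p of 0.010 in limma. The other called genes carry only locus numbers, and no function is given for them here.

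Several of the increases separated a clear signal in HH1 from a signal near background in MH63. LOC4347149 had a signal of 633 ± 13.9 (SD, n = 3) in HH1 and 28.3 ± 17.9 (SD, n = 3) in MH63. In MH63 1 of 3 arrays exceeded the reporter-probe level, and the probe set can also bind related transcripts. Other probe sets of that gene, not called, differed less, so the gene is not shown to be near background in MH63. They read 407 in HH1 and 283 in MH63, 133 and 53.6, and 61.3 and 35.4. Only in the last was MH63 at or below the reporter-probe level on all 3 arrays. LOC4350580 stood at 565 ± 30.1 against 45.2 ± 15.7, and LOC4350579, its neighbour in the gene annotation, at 432 ± 6.67 against 38.0 ± 17.3 (SD, n = 3 each), with 2 of 3 MH63 arrays above that level for both. LOC4350599 reached 1150 ± 65.9 in HH1 against 128 ± 62.0 in MH63 (SD, n = 3 each), a log2 change of 3.27. LOC4344033 rose by 3.58, LOC4350759 by 2.26 and LOC4347151 by 2.18 on the log2 scale, the first of these again from a probe set shared with related transcripts. In 4 of the 12 named increases the MH63 signal was at or below the reporter-probe level on all 3 arrays, so that only a bound on the fold is given. LOC4350740 was at least 5.93-fold higher in HH1, LOC9270101 at least 3.42-fold, LOC4350598 at least 2.64-fold and LOC4347147 at least 2.49-fold.

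Among the decreases, LOC4333210 had a signal of 5052 ± 47.6 (SD, n = 3) in MH63 and 2415 ± 207 (SD, n = 3) in HH1, a log2 change of -1.07 with an adjusted p of 0.022 in limma. LOC4340167 fell from 598 ± 65.0 to 135 ± 36.1 and LOC9269692 from 206 ± 18.5 to 65.1 ± 3.98 (SD, n = 3 each), both read from probe sets that can bind related transcripts. A second called probe set of LOC9269692, with a plain _at ID, also fell, from 83.1 ± 13.1 to 27.0 ± 1.49 (SD, n = 3 each), with HH1 at or below the reporter-probe level and an adjusted p of 0.020 in limma. Another probe set of that gene, below the brightness filter, went the other way. LOC4347112 fell by 1.06 on the log2 scale. The HH1 signal of LOC4344073 and LOC4350734 was at or below the reporter-probe level on all 3 arrays, and these genes were at least 2.73-fold and at least 4.34-fold lower in HH1, each from a probe set shared with related transcripts. LOC4337758 and LOC4347224 were next by p and did not pass, with adjusted p of 0.057 and 0.064 in limma. The former was at least 2.11-fold lower, with HH1 at or below the reporter-probe level on all 3 arrays, and the latter had a log2 difference of -1.28. Of the called probe sets without a gene, the 2 with the largest increase rose from 79.1 ± 42.3 to 830 ± 208 and from 42.9 ± 14.2 to 239 ± 56.0, and the only one that fell went from 135 ± 13.0 to 56.0 ± 5.23 (SD, n = 3 each).

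**Figure D1:**
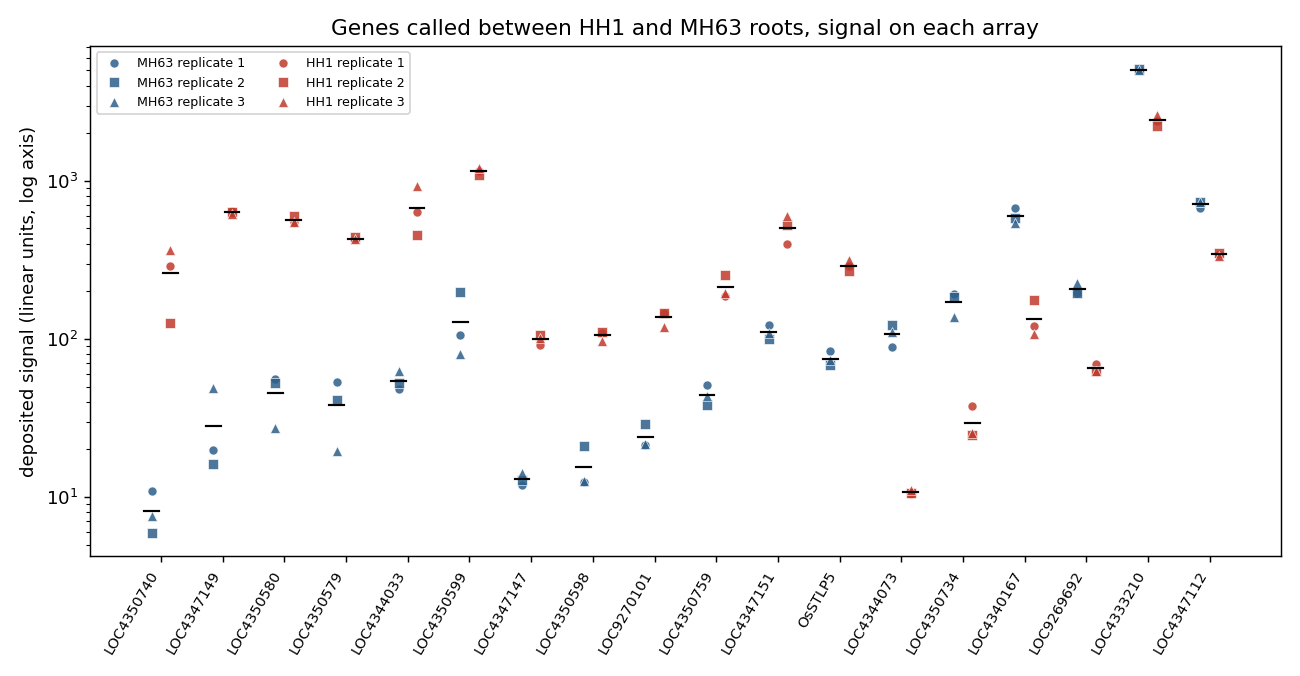
Deposited signal (linear units, log axis) on each of the 6 arrays for the 18 named genes past the test, HH1 in red and MH63 in blue, with a marker per replicate and a bar at the group mean. For each gene the groups do not overlap, which the rule for named genes required, as for LOC4333210 with 5052 in MH63 and 2415 in HH1.

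The count of called probe sets depended on single arrays. It was 0 without HH1 replicate 1 (843 at an unadjusted p under 0.05), 26 without HH1 replicate 2 and 306 without HH1 replicate 3. Without MH63 replicate 1 it was 1, without MH63 replicate 2 it was 20 and without MH63 replicate 3 it was 13. With no brightness filter the count was 54, in the brightest 25% 8, with array weights 50 and with a replicate block 17. LOC4347147 passed in all 10 alternatives that tested it, but it was below the filter in the brightest 25% and whenever an HH1 array was left out, and each of the other 20 named genes and probe sets lost its call in at least 1 alternative.

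In their group means, genes fixed as references were close to equal between the genotypes. EF-1-alpha, a translation elongation factor, had a signal of 12281 ± 598 in HH1 and 12043 ± 478 in MH63 (SD, n = 3 each). GAPC, a cytosolic glyceraldehyde-3-phosphate dehydrogenase, stood at 9728 ± 374 and 9373 ± 373, the actin AC7 at 7809 ± 732 and 7490 ± 389, and GAPC3 at 8396 ± 2881 and 8019 ± 1221 (SD, n = 3 each). None of these 4 passed the test, and the signs of EF-1-alpha, GAPC3 and AC7 turned in some alternatives. The 24 genes of the reference list had a median log2 difference of 0.03, and the list did not pass.

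To ask which processes differed, 35 lists of genes grouped by name were tested against all other genes, and 6 passed with camera's preset correlation, 5 higher and 1 lower in HH1. None of the 6 held with an estimated correlation, where the smallest adjusted p over all lists was 0.986, and fry called none. No list member passed the test over all probe sets. Adjusted over the list alone, 1 gene passed, DRM3 of the RNA silencing and DNA methylation list, named here after its values were seen, at 305 ± 14.1 in HH1 and 462 ± 23.8 in MH63 (SD, n = 3 each), with an adjusted p of 0.029 in limma.

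Genes of jasmonate synthesis and signalling, the wound and defence hormone pathway, were higher as a list, with 25 of 38 members above 0, a median log2 difference of 0.20 and an adjusted p of 3.3e-05 (camera). The p with an estimated correlation was 0.16 before adjustment. The values of HH1 split between replicates. OsJAZ3, a repressor that is itself induced by jasmonate, had a signal of 779 in HH1 replicate 1, 685 in HH1 replicate 2 and 96.0 in HH1 replicate 3, beside 105 ± 13.6 (SD, n = 3) in MH63. OsJAZ11 read 2459, 2261 and 605 on the same HH1 arrays against 642 ± 103 in MH63, and OsJAZ13 read 1666, 1562 and 427 against 454 ± 13.3 (SD, n = 3 each). AOS, the allene oxide synthase of jasmonate synthesis, read 570, 484 and 196 against 185 ± 0.78 (SD, n = 3).

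The full-size ABCG transporters, which export defence compounds and other substrates across the plasma membrane, were higher as a list, with 7 of 7 members above 0, a median of 0.57 and an adjusted p of 0.0013 (camera), and an unadjusted p of 0.14 with an estimated correlation. OsABCG36 read 1658, 1232 and 163 on HH1 replicates 1, 2 and 3 against 228 ± 72.7 (SD, n = 3) in MH63, and OsABCG44 read 1108, 918 and 95.9 against 140 ± 20.8 (SD, n = 3). OsABCG37 stood at 1351 ± 465 against 872 ± 52.4 and OsABCG48 at 855 ± 311 against 577 ± 41.1 (SD, n = 3 each). For both, HH1 replicate 3 lay below all MH63 arrays, at 822 and 526. The list of diterpenoid phytoalexin and gibberellin precursor synthesis was also higher, with 13 of 16 members above 0, a median of 1.08 and an adjusted p of 0.031 (camera), and an unadjusted p of 0.32 with an estimated correlation. The diterpene synthase OsDTS2 read 813, 828 and 26.2 on HH1 replicates 1, 2 and 3 against 52.8 ± 30.4 (SD, n = 3) in MH63. CYP76M8, a cytochrome P450 of phytoalexin synthesis, stood at 252 ± 68.4 against 185 ± 10.9 (SD, n = 3 each). The gibberellin enzyme OsCPS lay on the other side of 0, with a log2 difference of -0.30. For OsKAO, another gibberellin enzyme, HH1 was at or below the reporter-probe level on all 3 arrays and MH63 near it, so no change is given. Without HH1 replicate 3 the log2 differences became 2.81 for OsJAZ3, 2.86 for OsABCG44 and 4.20 for OsDTS2, and these genes then passed with adjusted p of 0.0042, 0.0047 and 0.039 in limma, which none of them did in any other alternative. Without HH1 replicate 1 the log2 differences were 1.30, 1.09 and 1.72, and without HH1 replicate 2 they were 1.39, 1.23 and 1.71, with adjusted p of at least 0.65 in limma. Without HH1 replicate 2 the jasmonate, ABCG and diterpenoid lists did not pass, and the diterpenoid list did not pass without HH1 replicate 1, MH63 replicate 1 or MH63 replicate 3 either.

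Phenylpropanoid and lignin genes were higher as a list by a small margin, with 19 of 29 members above 0, a median of 0.04 and an adjusted p of 0.036 (camera), and an unadjusted p of 0.036 with an estimated correlation. LAC10, a laccase, stood at 495 ± 107 in HH1 and 294 ± 23.6 in MH63, PAL06, a phenylalanine ammonia-lyase, at 839 ± 251 and 477 ± 58.3, and 4CLL4, a 4-coumarate-CoA ligase-like protein, at 1513 ± 327 and 1014 ± 48.8 (SD, n = 3 each). OsCAD8C, a cinnamyl alcohol dehydrogenase, was lower, at 68.7 ± 4.70 against 99.6 ± 8.14 (SD, n = 3 each). Genes of protein folding in the endoplasmic reticulum had 20 of 26 members above 0, a median of 0.07 and an adjusted p of 0.033 (camera), and an unadjusted p of 0.19 with an estimated correlation. OsPDIL2-3 and OsPDIL2-1, protein disulfide isomerases, had log2 differences of 0.18 and 0.20, OsDjB6, a DnaJ-type chaperone, 0.18, and OsbZIP50, a transcription factor of the unfolded protein response, 0.14. With quantile normalization neither of these 2 lists passed, and the phenylpropanoid list did not pass with no brightness filter or with a replicate block either. With 1 array left out, the phenylpropanoid list passed only without MH63 replicate 2 or MH63 replicate 3, and the endoplasmic reticulum list only without HH1 replicate 2.

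Green tissue markers, listed to detect shoot material in a root sample, were lower as a list in HH1, with 17 of 18 members below 0, a median of -0.63 and an adjusted p of 0.015 (camera), and an unadjusted p of 0.30 with an estimated correlation. PSB28, a photosystem II protein, stood at 59.9 ± 11.3 in HH1 and 82.2 ± 8.60 in MH63, and ISP at 81.1 ± 15.9 and 144 ± 57.1 (SD, n = 3 each). CHL1 stood at 71.6 ± 14.2 and 94.6 ± 10.2, and OsGLK2, a regulator of chloroplast development, at 35.6 ± 18.7 and 73.6 ± 43.8 (SD, n = 3 each). OsGLK2 lay below the reporter-probe level in HH1 replicates 1 and 3 and MH63 replicate 3, at 22.1, 27.8 and 25.8, so its difference is uncertain. The list mean, relative to each gene's mean over the 6 arrays, was 0.79, 0.92 and -0.87 in MH63 replicates 1, 2 and 3 and -0.53, 0.47 and -0.78 in HH1 replicates 1, 2 and 3. This list did not pass without HH1 replicate 1, HH1 replicate 3, MH63 replicate 1 or MH63 replicate 2. Fewer lists passed when single arrays were left out, 2 without HH1 replicate 1, 3 without HH1 replicate 3 and 2 without MH63 replicate 1. Without HH1 replicate 2 the number was 6, of which 2 were shared with the 6 above, and the reference list was then among those that passed.

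**Figure D2:**
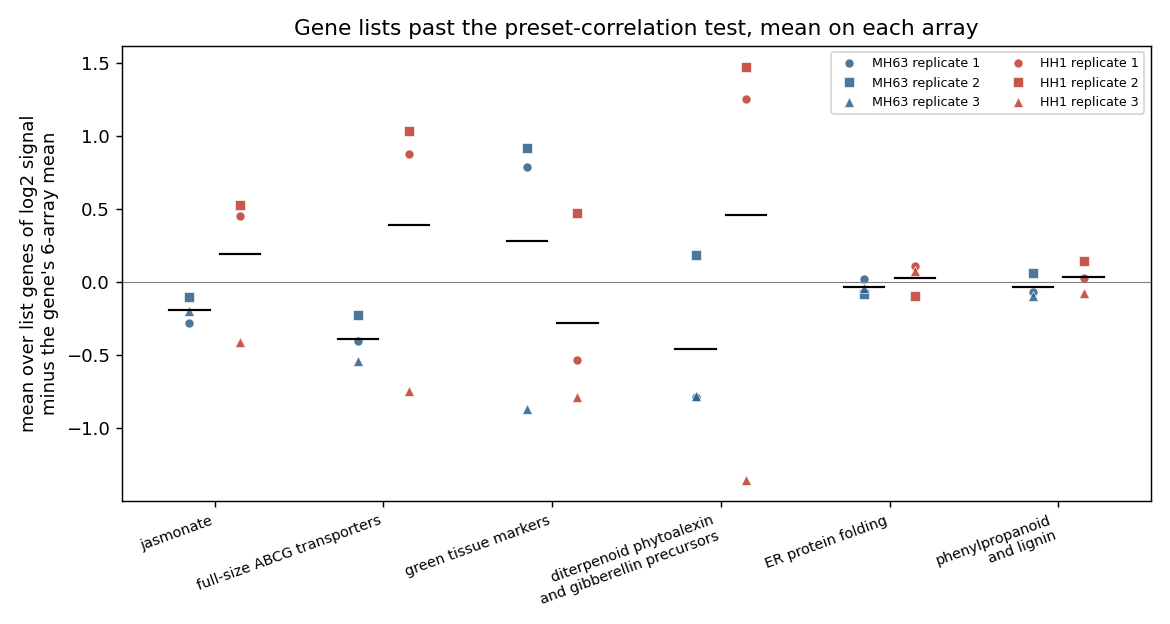
Mean over the genes of each list of log2 signal minus the gene's mean over the 6 arrays, for the 6 lists past camera with a preset correlation, HH1 in red and MH63 in blue, a marker per replicate and a bar at the group mean. In the jasmonate list HH1 replicates 1 and 2 lie at 0.45 and 0.53, while HH1 replicate 3 lies at -0.41, below all MH63 arrays.

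HH1 arrays correlated less with one another (median r 0.952) than arrays of different genotypes did (median r 0.960). Correlations of log2 signals over the tested probe sets, which are across probe sets and not independent replicates, were 0.93 to 0.97 among HH1 arrays, 0.97 to 0.98 among MH63 arrays and 0.95 to 0.98 between genotypes. The first principal component, with 43.6% of the variance, set HH1 replicate 2 (67.3) against HH1 replicate 3 (-45.2). HH1 replicate 2 also stood apart in ribosomal RNA, with an 18S signal of 3446 where the other arrays read from 811 in HH1 replicate 1 to 1457 in MH63 replicate 2. The groups did not overlap for 8.78% of tested probe sets, where chance gives 10%, and 4.01% had an unadjusted p under 0.05.

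Mean signals of the 64 reporter probe sets, which represent foreign marker genes, did not exceed 52.8 in either genotype. The groups did not overlap for 6 of them, where chance gives 6.4, and the smallest two-sided exact permutation p that 3 against 3 allows is 0.1. The groups overlapped for each of the 27 rice housekeeping controls, where chance gives 2.7 without overlap. For 4 of 86 spike-in and other controls they did not overlap, where chance gives 8.6. Some housekeeping controls had group means below the reporter-probe level and show little, such as AFFX-Os-ef1a-5_at at 28.5 in HH1 and 30.2 in MH63.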

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

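Among the probe sets below the brightness filter, which the main comparison left out, 7 read higher in HH1 than in MH63 with no overlap, all HH1 arrays above the reporter-probe level and a 4-fold limit on the measured signals, which was chosen after the data were seen. Only this direction was searched and no test was run, so dim probe sets lower in HH1 are not covered. MH63 means lay below the reporter-probe level in all 7, so no fold is given. GLUA-3, a glutelin of the seed, had a signal of 106 ± 52.8 in HH1 and 9.19 ± 2.15 in MH63 (SD, n = 3 each). The list of seed storage and aleurone markers did not pass, with 5 of 11 tested members above 0 and a median log2 difference of -0.012. Its mean, relative to each gene's mean over the 6 arrays, was 1.61, 0.012 and -1.22 in HH1 replicates 1, 2 and 3. Among 3 probe sets without a gene, the first stood at 85.4 ± 1.28 and 8.48 ± 2.81, the second at 53.1 ± 11.1 and 8.75 ± 2.25, and the third at 62.3 ± 10.1 and 13.7 ± 5.08 (SD, n = 3 each). LOC4347150 stood at 84.8 ± 14.8 and 12.6 ± 1.61, and LOC4350749 at 61.8 ± 15.1 and 11.6 ± 1.63 (SD, n = 3 each). The dim probe set of LOC9269692 stood at 51.9 ± 9.08 in HH1 and 11.2 ± 2.44 in MH63 (SD, n = 3 each), against the direction of that gene's 2 called probe sets.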

How the results depend on the processing

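The 32 called probe sets of the main comparison became 54 with no brightness filter, which tests more probe sets, 8 in the brightest 25%, which tests fewer, and 50 with array weights, where the cause was not tested. Leaving out 1 array gave 0 (without HH1 replicate 1, with 843 at an unadjusted p under 0.05) to 306 calls (without HH1 replicate 3), and the cause was not tested. Quantile normalization, median centring, the offset and no trend gave 32 to 40 calls. In every alternative each of the 32 that was still tested kept its sign and an unadjusted p under 0.05. The 32 were selected on the same arrays that the alternatives reuse, so this was nearly fixed in advance and is not independent support. The share of higher calls was 75% under each scaling. With a replicate block 17 probe sets were called, all among the 32. Same-numbered arrays deviated together with r of -0.12, 0.45 and 0.31 across probe sets for replicates 1, 2 and 3. HH1 replicates 2 and 3 matched their own number best, while HH1 replicate 1 matched MH63 replicate 3 best (r of 0.25). With 3 arrays per group this does not settle whether the numbers pair the samples. The 6 lists became 0 with an estimated correlation, which allows for members that vary together and whose power was not measured, and 0 with fry, which asks another question. Quantile normalization gave 4 lists, no filter 5, the block 5, the offset and the mean of probe sets 6 each, and leaving out 1 array 2 to 6. The phenylpropanoid list lost its call with quantile normalization, no filter and the block, and kept it with 1 array left out only without MH63 replicates 2 and 3. The endoplasmic reticulum list lost it with quantile normalization and with any array but HH1 replicate 2 left out. The jasmonate and ABCG lists lost it without HH1 replicate 2, the diterpenoid list without HH1 replicates 1 and 2 and MH63 replicates 1 and 3, and the green tissue list without HH1 replicates 1 and 3 and MH63 replicates 1 and 2. The cause was not tested. The direction of the 6 lists held in each of these alternatives, and lists were not run with median centring, the brightest 25%, no trend or array weights. Signs turned only for 3 reference genes, none called. GAPC3 read -0.11 with array weights and -0.24 to 0.18 with 1 array left out, EF-1-alpha -0.0020 to 0.067, and AC7 -0.018 to 0.10. Signals near the reporter-probe level limit what dim transcripts can show.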

Other observations

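Leaving out single arrays and splitting the arrays in other ways were planned before the data were examined, and the count of gene lists over splits was set before its result was seen, but how to read the count of called probe sets over splits was set after. The other tests below were chosen after the results were seen. With HH1 replicate 3 left out, 288 of the 306 called probe sets were higher in HH1. They included 6 of 38 jasmonate genes, among them OsJAZ10 and 2 genes that both carry the name OsJAZ11, 3 of 7 full-size ABCG transporters and 4 of 16 diterpenoid genes, CYP76M5, CYP76M6, OsKO4 and OsDTS2. Of 29 phenylpropanoid genes, 1 was called higher, Os4CL5. No green tissue marker and no gene of the endoplasmic reticulum list was among the higher or lower calls. These genes were named after their values were seen.

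Probe sets for genes of the rice blast fungus, present on the array as controls, read lower in HH1 without overlap for 5 of 10, where chance gives 1 without overlap in either direction. These 5 stand for only 2 genes, with 3 for actin and 2 for ef1a, so they are not independent. AFFX-Mgr-ef1a-3_at stood at 92.1 ± 13.5 in HH1 and 188 ± 48.7 in MH63, while AFFX-Mgr-ef1a-M_at stood at 31.1 ± 3.66 and 32.2 ± 5.68 (SD, n = 3 each). Group means of AFFX-Mgr-actin-3_at lay below the reporter-probe level in both genotypes, at 26.6 ± 2.59 and 32.2 ± 3.88 (SD, n = 3 each). For each gapdh probe set of the fungus the groups overlapped.

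The called genes lay close together in the gene order of the RefSeq annotation of ASM3414082v1. Of 20 called genes, 17 had another within 100 genes, in 5 runs, where random draws of 20 tested genes gave a median of 2 and at most 10 (permutation p = 1e-04, the smallest that 10000 draws can give). One run held LOC4350579, LOC4350580, LOC9270101, LOC4350598 and LOC4350599 within 29 annotated genes, all higher in HH1. Others held LOC4347112, LOC4347147, LOC4347149 and LOC4347151, or LOC4350734, LOC4350740, OsSTLP5 and LOC4350759, each with 3 genes higher and 1 lower, or LOC4344033 and LOC4344073, or the adjacent LOC4339056 and LOC4339057. Of the 4 dim genes above, LOC4347150 and LOC4350749 lie inside such runs, and GLUA-3 and LOC9269692 do not.

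Order by chance is argued against by that permutation p of 1e-04. Cross-hybridisation between near-identical genes known to the array's design is not decided. Of the 17 genes, 76.5% were called by a probe set with a plain _at ID, but most tested probe sets have such an ID. IDs ending in _x_at or _s_at made up 25% of the called probe sets and 21.8% of those tested. Taken over both directions, the calls were thus not concentrated in probe sets known to bind related transcripts. Shares were not compared for the decreases alone. Of the lower genes, LOC4340167, LOC4344073, LOC4350734 and LOC9269692 were read from such probe sets, the last also from a plain _at one. LOC4333210 and LOC4347112 were read from plain _at probe sets. Small sequence variants under single probe sets stay open. Of 4 uncalled probe sets from other consensus sequences of the clustered genes, 3 moved the same way at an unadjusted p under 0.05, but all 3 belong to LOC4347149. They rose by 1.31 and 0.53 on the log2 scale and at least 1.51-fold, where the called one read 633 against 28.3, and 2 of the 3 can bind related transcripts. The remaining one, of LOC4344033, differed by 0.44. For LOC4350599 the probe set from another consensus sequence was itself called, and 14 genes had no such probe set. A candidate explanation is that HH1 carries segments of another parental origin than this MH63 stock, but the 47 uncalled genes inside the runs had a median absolute t of 0.77 against 0.62 in random runs (permutation p = 0.11), which does not decide it. A second measure of the same genes, computed alongside, gave 14.9% with an unadjusted p under 0.05 against 3.85% in random runs (permutation p = 0.0023), and genotyping of both lines would be needed.

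The 6 gene lists may reflect genes that vary together between replicate samples and not with genotype. In 6 of the 6 the list means per array overlapped between genotypes. Chance gives groups without overlap in only 10% of cases, so this overlap cannot tell shared variation from chance or from a weak difference by genotype. In the jasmonate, ABCG and diterpenoid lists HH1 replicate 3 lay below all MH63 arrays. As many lists passed in 8 of the 10 splits of the arrays, with 6 in the real split and up to 11 in another, and 10 splits are too few for a share under 0.05. A difference by genotype in how readily these pathways are induced was not tested.

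For called probe sets, the real split gave 32 and the highest other split 138, so that 2 of the 10 splits gave as many, and again 10 splits are too few for a share under 0.05. The split with 138 set HH1 replicates 1 and 3 and MH63 replicate 3 against the rest, which points to a structure of the samples that crosses genotype. The 8 remaining splits gave 0 or 1.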
